A study of Mus musculus with 5 samples.

How the data were processed

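Hematopoietic stem and progenitor cells sorted by flow from crushed bones of C57BL6/J mice were profiled by droplet-based single-cell RNA sequencing, per the labels' protocols. The 5 libraries came from wild-type mice at 2 months (WT_2M, 1 library) and 6 months (WT_6M, 1 library) and from Dnmt3a knockout mice at 2 months (KO_2M, 2 libraries) and 6 months (KO_6M, 1 library), and the labels give male sex for each. The surface markers of the sort gate, the part of Dnmt3a that was deleted and the number of mice behind a library are not given in the sources used here. Nothing in the labels says that libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

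The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, in 1 table per library, and whole numbers throughout. The labels' protocols name the 10x Genomics 3' kit, version 2. The submitters' processing notes name CASAVA, TopHat2, HTSeq and Seurat and the builds mm10 and GRCm38, with no role, order or version. The counting program, the annotation release and the rule by which the authors called cells are not given in the sources used here. The 2-month tables listed 28692 gene symbols and those of 6 months 31053, so the gene models behind the deposited counts differed between the ages. Only the 27292 symbols found in all tables entered the fits, and they held 98.4% to 98.5% of the counts of each library. Symbols listed at 1 age only numbered 1400 at 2 months and 3761 at 6 months.

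Deposited barcodes per library numbered 8013 to 8716 and total counts 78194582 to 100017088. Cells were kept with at least 500 genes detected and under 10% of UMIs from mitochondrial genes. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest-scoring cells were removed up to a share of 0.8% per 1000 cells, which took 6.14% to 6.73% of the cells. This left 7199 to 7842 cells per library, with a median of 7577 to 10163 UMIs per cell. Knockout libraries were deeper per cell than the wild-type library of the same age. Shares carry exact Clopper-Pearson 95% intervals and sums of counts exact Poisson 95% intervals, and a count of 0 was read as a limit of 3 counts. These intervals and limits cover counting error only.

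Cells of all libraries were clustered together without integration, on counts per 10000 after a log transform, 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, scikit-learn 1.9.0). Clusters were named "X-like" from fixed marker lists. A name needed at least 3 markers of 1 cell type among the top 50 genes by fold, with at least 2 among the top 10; other clusters stayed unnamed. This naming rule was set after the data were seen. So were 2 more clusterings. One centred each gene within its library beforehand. The other left out the cell type markers and the Hox, Meis and stem-cell transcription factor list, which left 1837 variable genes. Shares of the main progenitor classes are given from the clustering without marker genes beside those of the planned clustering, because marker genes differed between the genotypes. To compare shares of cells with a UMI across depths, each cell was thinned to 2000 UMIs, which left out 34 to 63 shallower cells per library.

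For each comparison, counts were summed over all kept cells of a library and tested across libraries with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F test, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype and age coefficients came from 1 model of both factors over all 5 libraries, with 2 residual degrees of freedom. The interaction came from a model with 1 mean per group, with 1 residual degree of freedom. The same genotype test was run per cell class with at least 50 kept cells in every library. Same-age pairs of libraries are described by log2 ratios of CPM (counts scaled to a common total per library). A test of genotype within each age, from the model with 1 mean per group, was added after the data were seen. Since only KO_2M had replicates, it assumes that the groups with a lone library vary like KO_2M. Ratios summarised over gene lists had 1 CPM added to each value. Mean shares were compared by a two-sided exact permutation test over all 10 splits of the libraries, which cannot give a p under 0.1.

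Gene lists for cell types and pathways were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation, camera uses the residual degrees of freedom of the fit, 2 or fewer here. A call after adjustment was then hardly possible, so its absence does not count against a list. For age even the sex-linked check genes (median log2 fold change −7.90) had camera Benjamini-Hochberg adjusted p = 0.961 with an estimated correlation. Benjamini-Hochberg adjustment ran over the 43 lists with enough measured genes. The rule for named genes took, for genotype, the genes past the threshold with a mean of at least 10 CPM and the same sign in all 3 same-age pairs, ranked by fold change. If fewer than 6 passed, the rule took the 10 genes of smallest p in each direction, given as values that did not pass; the CPM and sign conditions were kept for these. For age it took the 8 largest and 8 smallest fold changes, and per cell class 3 in each direction. For each list described it took the 2 to 4 members of smallest p, and Dnmt3a was always named. The samples, tests, marker lists, gene lists, alternatives (except those named below) and this rule were fixed before the data were examined.

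Alternatives covered DESeq2 1.42.0 as the test, DESeq2 size factors, no low-count filter, all barcodes, no doublet removal, thinned cells, equal class makeup, models without the other factor, other clustering resolutions, other CPM minimums and each library left out in turn. With either KO_2M library left out, each group had 1 library, and the spread came only from departures from additive age and genotype effects. Leaving out KO_6M or WT_6M gave nearly the same genotype test, of the 2-month libraries alone. Leaving out WT_2M or WT_6M gave nearly the same age test, of the knockout libraries alone. Equal class makeup with the added clusterings, share tests in the clustering without marker genes and a simulation of same-age pairs were chosen after the data were seen. So was the rule that an equal class makeup decides nothing for a list whose own genes helped to build the classes.

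The fits were tested on simulated counts with the means, depths and fitted dispersions of the real libraries and 200 changed genes. In the genotype simulation, edgeR recovered 61% of the 2-fold and 77% of the 4-fold changes among 14424 genes, with 18 false calls. DESeq2 recovered 67% and 79%, with 52 false calls. In the age simulation edgeR recovered 63% and 80%, with 17 false calls, and DESeq2 72% and 86%, with 50. In the interaction simulation over 14940 genes, edgeR recovered 3% of the 2-fold and 53% of the 4-fold changes, with 53 false calls, and DESeq2 1% and 45%, with 24. In each of these simulations, with either tool, false calls were a larger share of all calls than the adjusted threshold allows. With no gene changed, edgeR made 4 false calls for genotype, 3 for age and 11 for the interaction. The simulated counts had no shifts shared by genes of a cell type. The recovered percentages can therefore overstate how many changes the tests would find in the real libraries. The 2 knockout libraries at 2 months were treated as separate samples. They differed far beyond counting noise (chi-square per degree of freedom 123), which does not show that they came from separate animals. Positions are from the GENCODE annotation of GRCm38. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.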

Results

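Sorted mouse bone-marrow stem and progenitor cells from Dnmt3a knockouts were compared with wild-type cells of the same ages, 2 months and 6 months, in 2 wild-type and 3 knockout libraries. Dnmt3a encodes a de novo DNA methyltransferase, and the series title states an interest in markers of the pre-leukemic state. The wild-type libraries held 81402989 UMIs at 2 months and 78194582 at 6 months. Replicates 1 and 2 of the 2-month knockout held 92236414 and 100017088 UMIs, and the 6-month knockout library 93861155. After filtering, 7367 and 7562 wild-type cells and 7333, 7842 and 7199 knockout cells remained, in the same order.

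Dnmt3a transcripts were lower in each knockout library than in the wild-type library of the same age. The gene lies at chromosome 12, 3806007 to 3914443, plus strand, in GRCm38. Its level was 47.8 CPM (exact Poisson 95% interval 46.3 to 49.5) in WT_2M and 55.4 CPM (53.6 to 57.2) in WT_6M. In the knockout it was 25.8 CPM (24.7 to 26.9) in replicate 1 and 17.4 CPM (16.5 to 18.3) in replicate 2 at 2 months, and 26.2 CPM (25.1 to 27.4) at 6 months. These levels were 53.9%, 36.3% and 47.3% of the same-age wild type. A Dnmt3a UMI was found in 34.8% and 36.6% of wild-type cells and in 24.0%, 16.7% and 24.6% of knockout cells. After thinning to 2000 UMIs per cell the shares were 9.85% and 10.96% against 6.77%, 4.20% and 5.84%. Macrophage-like cells carried a UMI in 52.6% and 28.6% of 38 and 56 wild-type cells and in 25.8%, 12.7% and 23.9% of 62, 55 and 46 knockout cells. Median depths there were 5198 to 6387 UMIs against 7577 to 10163 over all cells. The share over all cells lay within or under the exact binomial interval of the macrophage-like share in each library. These cells therefore give no background level, and free RNA from other cells would enter CPM levels and shares alike. Across all genes the Dnmt3a difference did not pass (log2 fold change −1.05, SE 0.15, edgeR Benjamini-Hochberg adjusted p = 0.322, lower in 3 of 3 pairs). It passed without KO_2M replicate 1, but that fit left 1 library per group and so held no replicates. Because the labels do not give the deleted part of the gene, and 3' tags can lie outside it, the remaining transcripts say nothing about residual protein function.

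**Figure D1:**
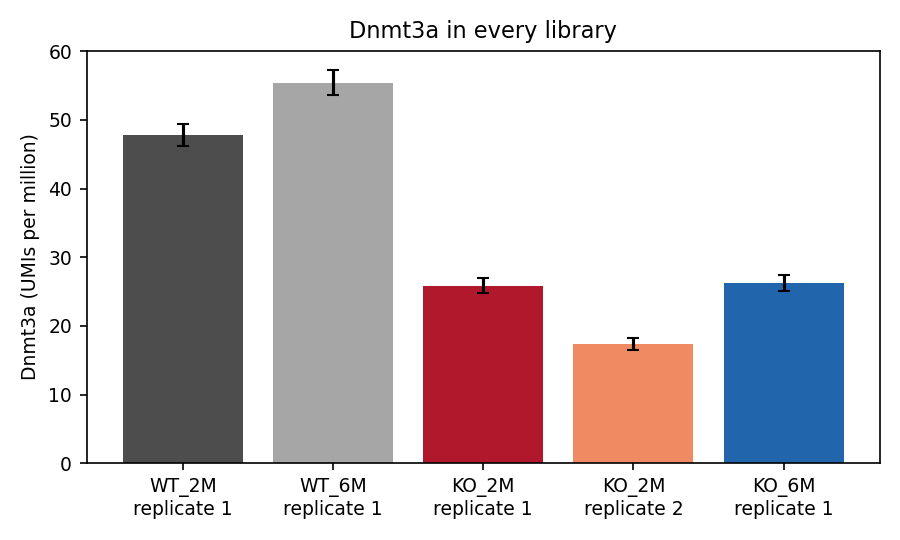
Dnmt3a in CPM (UMIs scaled to a common total) for each library, with exact Poisson 95% intervals of the counts (bars start at 0). The wild-type libraries stood at 47.8 and 55.4 CPM and the 3 knockout libraries between 17.4 and 26.2 CPM.

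Clusters named from stem-cell markers held smaller shares of the knockout cells, and megakaryocyte progenitor-like clusters larger shares, at both ages, although these shares did not pass a test. In the clustering without marker genes, HSC-like cells (hematopoietic stem cells) made up 48.0% (46.9 to 49.2) of WT_2M cells against 24.5% (23.5 to 25.5) and 1.76% (1.48 to 2.08) of KO_2M replicates 1 and 2. At 6 months they made up 28.2% (27.2 to 29.2) of wild-type and 13.04% (12.3 to 13.8) of knockout cells. Megakaryocyte progenitor-like cells made up 5.15% of WT_2M against 6.40% and 17.4% of the 2-month knockout, and 4.602% of WT_6M against 10.3% of KO_6M. Neutrophil and monocyte progenitor-like cells together made up 5.33% of WT_2M, 5.51% and 30.8% of KO_2M replicates 1 and 2, 1.28% of WT_6M and 14.7% of KO_6M. B-cell progenitor-like cells made up 0.407% and 0.476% of wild-type and 1.95%, 0.778% and 1.54% of knockout cells, and erythroid progenitor-like cells 2.43% and 1.10% against 5.47%, 3.70% and 1.67%. Many cells of KO_2M replicate 2 lay in clusters with interferon-stimulated top genes. Cluster 6 held 1965 of them among its 2244 cells and stayed unnamed with HSC as its closest type (2 markers), so 1.76% does not mean that stem-like cells were nearly absent there. Cluster 10 held 1358 cells of KO_2M replicate 2 among its 1517. It was named neutrophil progenitor-like from 3 markers and had Ifi27l2a and Isg15, both interferon-stimulated, among its top genes.

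The planned clustering gave HSC-like shares of 32.2% and 22.5% in wild type against 8.59%, 0.561% and 8.92% in the knockout, a difference in means of −21.3 percentage points. Here too, unnamed clusters had HSC as their closest type: cluster 5, with 1734 of 1910 cells from KO_2M replicate 2, and cluster 0, with 1875 WT_2M and 2181 KO_2M replicate 1 cells. In the same clustering, megakaryocyte progenitor-like cells made up 6.58% and 6.53% of wild-type and 8.09%, 18.3% and 11.8% of knockout cells. Neutrophil and monocyte progenitor-like cells made up 4.79% and 1.56% against 4.73%, 16.9% and 17.8%, so the share in KO_2M replicate 2 depended on the clustering. Erythroid progenitor-like cells made up 2.44% and 1.10% against 5.48%, 3.81% and 1.63%, and B-cell progenitor-like cells 0.407% and 0.476% against 1.96%, 0.778% and 1.53%. Planned cluster 2 held most of the HSC-like cells at 2 months and cluster 3 most of them at 6 months, so shares are set side by side within an age. The two-sided exact permutation p over the 10 splits was 0.1 for HSC-like cells in the planned clustering, the smallest these 5 libraries can give, and 0.2 without marker genes. For megakaryocyte and B-cell progenitor-like cells it was 0.2 in both clusterings, for erythroid ones 0.3 in both, and for neutrophil and monocyte ones 0.3 in the planned clustering and 0.2 without marker genes. The neutrophil and monocyte shares were carried by KO_2M replicate 2 and KO_6M, since replicate 1 lay within 0.176 percentage points of WT_2M in both clusterings. With library-centred clustering, replicate 1 was at 5.28% against 4.81% in WT_2M. Requiring at least 1000 genes and under 5% mitochondrial UMIs kept 139 to 5409 cells per library and gave an HSC-like difference of −0.845 percentage points. HSC-like cells then made up 2.19% and 0.719% of wild-type against 0.979%, 0.166% and 0.680% of knockout cells. They failed this filter more often than other cells, so their shares depend on it. Median mitochondrial percentages over all barcodes were 5.99 and 7.12 in wild type against 5.56, 4.70 and 6.39 in the knockout. With the stricter filter megakaryocyte progenitor-like cells made up 14.65% of WT_2M and 13.7% of KO_2M replicate 1, so the direction turned in this pair. The erythroid (−1.64) and B-cell (−1.55) differences in mean share reversed. Neutrophil and monocyte progenitor-like cells then made up 9.26% of WT_2M and 5.99% of KO_2M replicate 1. The sort gate is not given and can set these shares.

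**Figure D2:**
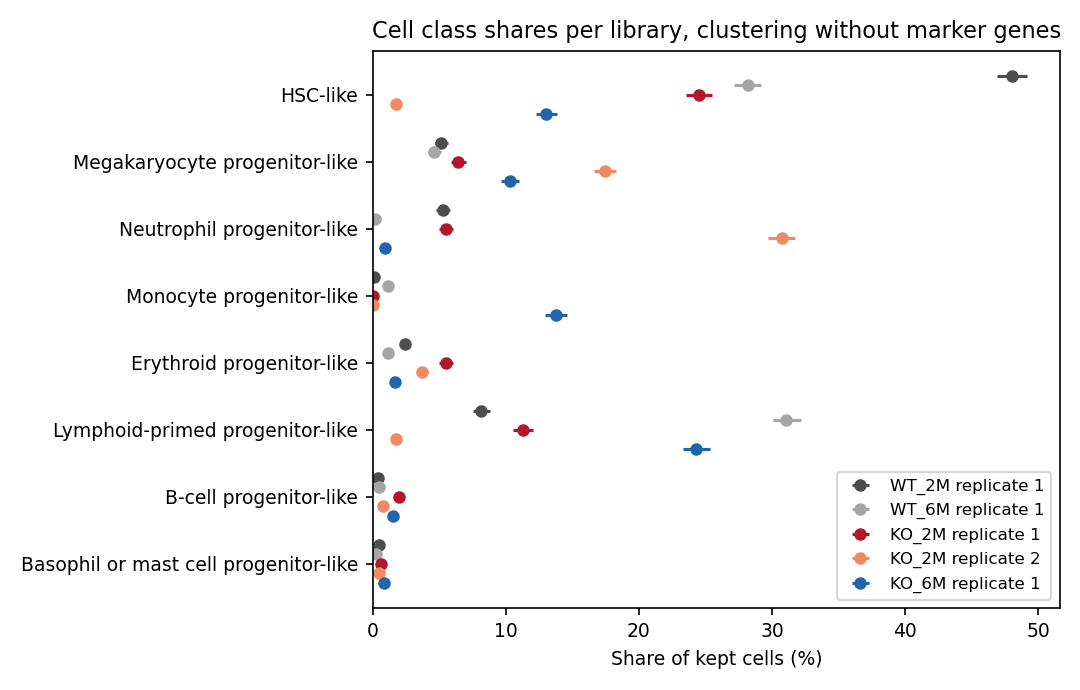
Share of kept cells (percent) per library for 8 named classes in the clustering without marker genes, with points coloured by library and exact binomial 95% intervals. HSC-like cells ranged from 28.2% to 48.0% in the wild-type libraries and from 1.76% to 24.5% in the knockout libraries.

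Over all cells, genes of cell division stood higher in the knockout libraries and genes expressed in stem cells lower, although no single gene passed the test. Ccnb1, the main mitotic cyclin, was at 48.4 and 61.3 CPM in wild type against 77.6, 70.2 and 100 CPM in the knockout (log2 fold change 0.73, SE 0.09). Aurkb, a kinase of the chromosomal passenger complex, gave 0.67 (SE 0.09), Plk1, a mitotic kinase, 0.73 (SE 0.10), and Ccna2, the S and G2 cyclin, 0.62 (SE 0.09). The metallothionein gene Mt1 gave 0.84 (SE 0.10) and Bcl2l12 0.76 (SE 0.09). Kif15, Kif22, Ncapg and Kpna2 filled the other higher places, with 0.57 to 0.95. Among the lower genes, the sulfotransferase gene Sult1a1 stood at 37.6 and 28.4 CPM against 8.32, 4.69 and 9.46 CPM (log2 fold change −2.07, SE 0.29), and Clec1a at 27.6 and 20.4 against 5.85, 5.16 and 9.04 CPM (−1.78, SE 0.26). Rgs1, a regulator of G-protein signalling, gave −1.18 (SE 0.16) and Tnip3 −1.37 (SE 0.18). Rhof, Ccdc112 and Stxbp4 gave −0.78 to −0.96. The immunoglobulin heavy-chain gene Ighg2b was at 46.3 and 92.5 CPM against 2.51, 0.605 and 1.5 CPM (−5.28, SE 0.58). Plasma cell-like cells made up 0.475% and 0.251% of wild-type cells against 0.191% and 0.013% of the 2-month knockout libraries and 0 of 7199 KO_6M cells, which allows up to 0.0417%.

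Of 14424 genes tested for genotype with edgeR, 0 were higher and 0 lower after Benjamini-Hochberg adjustment (smallest adjusted p = 0.322). At an unadjusted p under 0.05 there were 1054 higher and 1091 lower genes, where 721 in total would be expected by chance, and DESeq2 called 182 higher and 176 lower. Leaving out KO_2M replicate 1 raised the edgeR count, but fits without either KO_2M library left 1 library per group and so held no replicates. With cells thinned to 2000 UMIs, 1 gene, Ighg2b, passed.

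Lists of stem-cell genes were lower in the knockout by camera with the preset correlation (Benjamini-Hochberg adjusted p = 3.69e-05 for HSC markers). Neither these nor the other lists in this paragraph were called with an estimated correlation (camera Benjamini-Hochberg adjusted p = 0.812 with an estimated correlation). Of 14 measured HSC markers, 12 had negative log2 fold changes with a median of −1.03, and 10 were lower when adjusted over the list alone against 0 over all genes. Sult1a1, Pdzk1ip1 (93.3 and 82.2 CPM against 38.4, 26.7 and 45.8 CPM), the endothelial and stem-cell adhesion gene Esam and Hoxb5 had the smallest p. Of 29 Hox, Meis and stem-cell transcription factors, 28 were negative (median −0.43), and 7 were lower adjusted over the list alone and 0 over all genes. Gata3 gave −0.70 (SE 0.11), Hoxb6 −2.07 (SE 0.37) from 1.76 and 2.17 CPM in wild type, and Pbx3 −0.59 (SE 0.12). Imprinted genes, 18 of 20 negative with a median of −0.86, included the cell-cycle inhibitor Cdkn1c (−1.60, SE 0.32), Meg3 (−1.60, SE 0.41) and Grb10 (−0.85, SE 0.21). Immediate early genes, which also respond to tissue handling, had 22 of 25 members negative (median −0.43), with Ier2, Ppp1r15a, Dusp1 and Egr1 leading. MHC class II genes had 10 of 10 negative (median −0.49), with H2-Aa at 190 and 97.7 CPM against 119, 35.2 and 48.6 CPM. p53 targets had 15 of 20 negative (median −0.29), among them Plk2, the proapoptotic gene Bbc3 and Gdf15. Adjusted over the list alone, 3 p53 targets and 0 of the imprinted, immediate early and MHC class II genes were lower.

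Lists of proliferation and biosynthesis genes were higher by camera with the preset correlation (Benjamini-Hochberg adjusted p = 4.86e-23 for G2 and M phase genes). With an estimated correlation none was called (camera Benjamini-Hochberg adjusted p = 0.812 with an estimated correlation). All 52 measured G2 and M phase genes were positive, with a median of 0.50, and 44 were higher adjusted over the list alone against 0 over all genes. Birc5 stood at 131 and 137 CPM in wild type against 192, 190 and 228 CPM, and Aurkb, Cdca3 and Bub1 gave 0.57 to 0.69. All 43 S phase genes were positive (median 0.40), and 30 were higher adjusted over the list alone against 0 over all genes. Rrm2, a subunit of ribonucleotide reductase, gave 0.68 (SE 0.12), E2f8 0.63 (SE 0.10) and Clspn 0.51 (SE 0.09). All 67 oxidative phosphorylation genes (median 0.30), all 31 ribosome biogenesis genes (median 0.33) and 50 of 61 replication-dependent histone genes (median 0.35) were positive, with 0 past the threshold over all genes or adjusted over the list alone. The ribosome biogenesis median log2 ratio was 0.32 and 0.56 in the 2-month pairs and 0.03 at 6 months. Examples were Cox6a1 (0.41, SE 0.11), Npm1 (0.48, SE 0.14) and the linker histone gene Hist1h1b (0.89, SE 0.14). Knockout libraries were also deeper per cell, with medians of 8823 to 10163 UMIs against 7577 and 7594.

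Markers of other lineages differed less evenly between the pairs. Interferon-stimulated genes had 38 of 43 members positive (median 0.63), but the median log2 ratio was −0.22 in KO_2M replicate 1, 0.91 in replicate 2 and 0.45 in KO_6M. Ifi27l2a was at 18.3 and 20.2 CPM in wild type and 19.6, 158 and 105 CPM in the knockout. Monocyte progenitor markers (median 1.48) had pair medians of −0.37, 0.96 and 2.13, with Csf1r at 3.92 and 2.56 CPM against 3.16, 12.2 and 17.2 CPM. B-cell progenitor markers (median 0.95) had pair medians of 1.47, −0.35 and 0.80, with Ebf1 at 12.3 and 12.5 CPM against 45.1, 10.5 and 28.0 CPM. Macrophage markers (median 0.64) had pair medians of 0.27, −0.19 and 0.56 and were led by the complement genes C1qa, C1qb and C1qc. None of the members of these 4 lists passed over all genes or adjusted over the list alone. Neutrophil progenitor markers did not pass (median 0.90, camera Benjamini-Hochberg adjusted p = 0.0789), with Mpo at 537 and 275 CPM against 508, 1119 and 1274 CPM. Neither did plasma cell markers (median −0.79, camera Benjamini-Hochberg adjusted p = 0.082). Without KO_2M replicate 1 both were called with the preset correlation (camera Benjamini-Hochberg adjusted p = 0.000569 and 0.00026), and neither with an estimated correlation (adjusted p = 0.802 with an estimated correlation). Without WT_2M the neutrophil progenitor list was called too (camera Benjamini-Hochberg adjusted p = 7.2e-05, and 0.944 with an estimated correlation).

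With the preset correlation, camera called 15 lists, from the G2 and M phase genes (Benjamini-Hochberg adjusted p = 4.86e-23) to the monocyte progenitor markers (0.022). No list was called with an estimated correlation, where so few residual degrees of freedom made a call hardly possible. The interferon list had adjusted p = 0.889 and the other 14 had adjusted p = 0.812 with an estimated correlation in camera, and fry called 0. The interferon list also lost its call without KO_2M replicate 2 (camera Benjamini-Hochberg adjusted p = 0.381). The monocyte list lost it without KO_2M replicate 2 (0.13), KO_6M (0.637) or WT_6M (0.639), the macrophage list without KO_6M (0.217) or WT_6M (0.218), and the ribosome biogenesis list without WT_2M (0.284), by the same adjusted p. Without WT_2M the immediate early (0.0742), MHC class II (0.156) and p53 (0.0885) lists lost it too, as did p53 targets without KO_2M replicate 1 (0.123). The B-cell list lost it without KO_2M replicate 1 (0.0817), KO_6M (0.093) or WT_6M (0.0885). Fits without KO_6M and without WT_6M both test the 2-month libraries alone, so such losses count once. Other lists gained a call without 1 library. These were heat shock (0.014) and glycolysis genes (0.0497) without KO_2M replicate 1, erythroid markers (0.012) without replicate 2, and basophil or mast cell (4.99e-05) and eosinophil progenitor markers (0.000192) without WT_2M, all higher. With an estimated correlation none of these was called (camera Benjamini-Hochberg adjusted p of at least 0.802 with an estimated correlation). An equal class makeup decides nothing for the HSC, p53, macrophage, monocyte and B-cell lists, whose calls differed between planned and library-centred classes. Of their genes, 13 of 14, 5 of 20, 8 of 8, 11 of 12 and 12 of 12 were among the variable genes that built the classes. The B-cell list turned to lower with planned (0.28) and library-centred classes (0.0419, and 0.737 with an estimated correlation), by camera Benjamini-Hochberg adjusted p. Plasma cell markers, which also helped to build the classes, were called lower with both (0.00964 and 0.00334, and 0.783 and 0.719 with an estimated correlation). Cholesterol synthesis genes were called lower with planned classes (0.0229, and 0.783 with an estimated correlation), by the same adjusted p. So were dendritic cell markers (0.000953) and lymphoid-primed progenitor markers (0.0159) with library-centred classes, again by the same adjusted p. Neither was called with an estimated correlation (camera Benjamini-Hochberg adjusted p = 0.719 with an estimated correlation).

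Surface antigens of progenitors and leukaemia did not move as a group (61 genes, 33 positive, median 0.01, camera Benjamini-Hochberg adjusted p = 0.847). Within it Procr, the endothelial protein C receptor found on stem cells, stood at 52.7 and 49.2 CPM in wild type against 20.4, 8 and 18.4 CPM in the knockout (log2 fold change −1.63, SE 0.36). Cd63 gave −0.46 (SE 0.10), while Cd48, a marker of progenitors past the stem-cell stage, gave 1.06 (SE 0.32). Of these genes 0 passed over all genes and 0 adjusted over the list alone. Among 18 DNA methylation and demethylation enzymes, only Dnmt3a was lower adjusted over the list alone, and 0 passed over all genes. Dnmt1, the maintenance methyltransferase, gave 0.51 (SE 0.14) and Uhrf1, its cofactor, 0.42 (SE 0.10), and the list did not pass (median 0.18, camera Benjamini-Hochberg adjusted p = 0.116). The 19 measured neighbours of Dnmt3a on chromosome 12 had a median of 0.05 (camera Benjamini-Hochberg adjusted p = 0.242), with 0 past the threshold over all genes and 1, Mfsd2b, higher adjusted over the list alone.

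**Figure D3:**
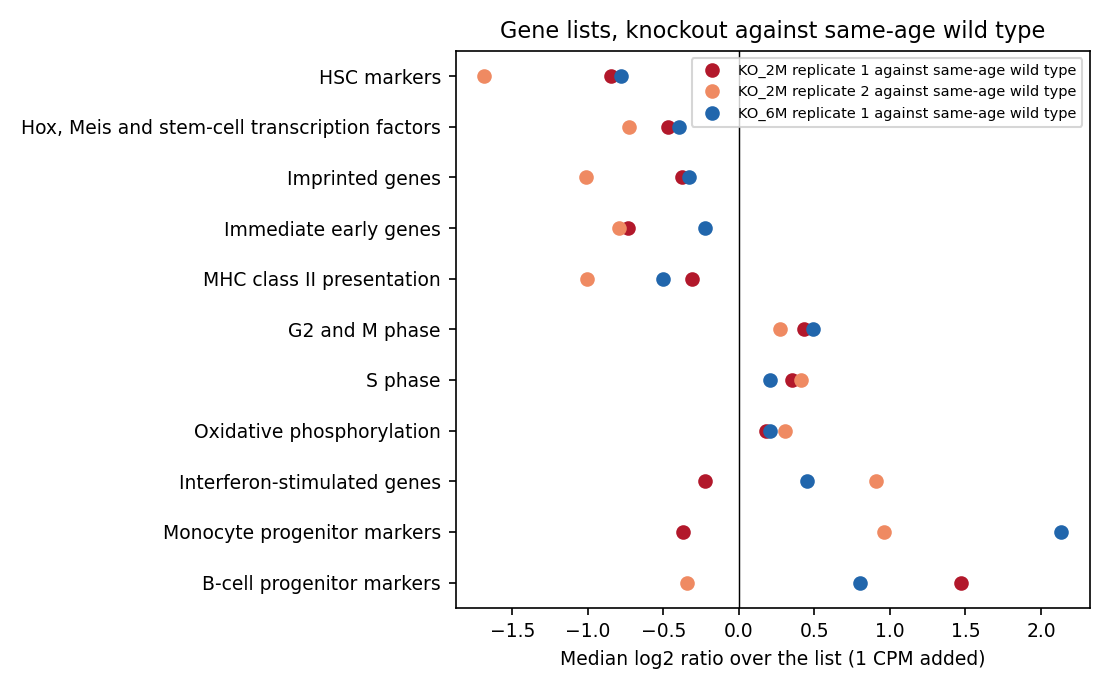
Median log2 ratio of CPM (1 CPM added) over each of 11 gene lists, with 1 point for each knockout library against the wild-type library of its age. HSC markers lay at −0.85, −1.69 and −0.78 and G2 and M phase genes at 0.43, 0.27 and 0.49, while interferon-stimulated genes lay at −0.22, 0.91 and 0.45.

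Few genes differed at least 2-fold in the same direction in every same-age pair. Of 6081 genes at a mean of at least 20 CPM, 0 were at least 2-fold higher and 8 at least 2-fold lower in all 3 same-age pairs. The 8 were Ighg2b, Jchain and Igkc, which encode immunoglobulin chains or their joining chain, and Procr, Mmrn1, Itsn1, Tnip3 and Rgs1. Igkc was at 4199 CPM in WT_2M against 1636 and 85.7 CPM in the 2-month knockout, and at 1614 against 7.95 CPM at 6 months. Mmrn1 was at 66.6 and 60.2 CPM in wild type against 27.0, 8.96 and 28.2 CPM. The 2 pairs at 2 months share WT_2M. Simulated libraries with no genotype difference, a check added after the data were seen, gave a median of 1 gene and at most 5 lower in all 3 pairs over 100 draws. Each gene was drawn on its own, so shifts shared by genes of 1 cell type could not arise. The 8 genes are therefore not shown to exceed chance. A minimum of 5 CPM gave 24 lower genes and of 100 CPM 2. Between the 2 knockout libraries at 2 months, 92 genes differed at least 2-fold. Across genes, which are not independent replicates, the log2 ratios at 6 months correlated with those of KO_2M replicate 1 at Pearson 0.405 and Spearman 0.546, and with those of replicate 2 at 0.715 and 0.682, with no library in common. A test within each age was added after the data were seen, with the lone libraries assumed to vary like the others. Of 14940 genes tested with edgeR, 0 were higher and 0 lower at either age after Benjamini-Hochberg adjustment (smallest adjusted p = 0.377 at 2 months and 1 at 6 months). At 2 months 731 genes had an unadjusted p under 0.05 and at 6 months 266, against 747 expected by chance, and DESeq2 called 2 higher and 33 lower, and 13 higher and 2 lower.

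Whether the genotype difference itself differed between ages was tested with the interaction. Sex-linked transcripts (below) and gene models differed along with age, so the interaction cannot tell age apart from these. Fos and Egr1 encode immediate early transcription factors. Fos stood at 41.5 CPM in WT_2M against 7.37 and 7.44 CPM, and at 6.69 CPM in WT_6M against 7.33 CPM in KO_6M. Egr1 stood at 63.4 CPM against 10.2 and 7.44 CPM at 2 months and at 13.6 against 8.98 CPM at 6 months. The granule protein genes Elane and Prg2 differed more at 6 months, with Elane at 532 CPM against 398 and 489 CPM at 2 months and at 86.7 against 409 CPM at 6 months. These genes were chosen after their values were seen. Of 14940 genes tested with edgeR, 0 were higher and 0 lower after Benjamini-Hochberg adjustment (smallest adjusted p = 1), 101 had an unadjusted p under 0.05 against 747 expected by chance, and DESeq2 called 8 higher and 0 lower. With the preset correlation, camera called 10 lists for the interaction, led by ribosome biogenesis (Benjamini-Hochberg adjusted p = 1.1e-08, median −0.45), monocyte progenitor markers (4.5e-05, median 1.83) and immediate early genes (5.39e-05, median 0.47). None of the 10 was called with an estimated correlation (camera Benjamini-Hochberg adjusted p = 0.982 with an estimated correlation), and fry called 1, the eosinophil progenitor markers (Benjamini-Hochberg adjusted p = 0.034).

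Within cell classes, Dnmt3a was lower in the knockout in each of the 5 classes tested. Its log2 fold change was −1.12 (SE 0.15) in megakaryocyte progenitor-like, −1.15 (SE 0.17) in lymphoid-primed progenitor-like, −1.30 (SE 0.21) in monocyte progenitor-like, −0.92 (SE 0.28) in erythroid progenitor-like and −0.89 (SE 0.14) in unnamed cells. In lymphoid-primed progenitor-like cells Cd74, the MHC class II invariant chain, gave −1.41 (SE 0.21) and Rgs1 −0.95 (SE 0.18). No gene passed in any of these classes with edgeR after Benjamini-Hochberg adjustment (smallest adjusted p = 0.134). Genes at an unadjusted p under 0.05 numbered 191, 350, 577, 429 and 443 in erythroid, lymphoid-primed, megakaryocyte, monocyte and unnamed cells, and DESeq2 called 0, 1, 3, 0 and 12. Without either KO_2M library, edgeR called other numbers of genes in most classes, but these fits left 1 library per group and no replicates. Without WT_2M it called 24 genes in lymphoid-primed cells, and without KO_6M 1 in monocyte progenitor-like cells. In other clusterings Dnmt3a itself passed within classes. By edgeR Benjamini-Hochberg adjusted p this held for lymphoid-primed cells at resolution 0.5 (0.0237) and 2 (0.00667), and for megakaryocyte cells at 0.5 (0.00844), 2 (0.00568) and with library-centred clustering (0.0266). Library-centred clustering, added after the data were seen, also gave 2 higher genes in HSC-like cells, Hells (1.62, SE 0.19, adjusted p = 0.0271) and Mcm5 (1.37, SE 0.18, adjusted p = 0.0435). These are edgeR values with Benjamini-Hochberg adjustment. The HSC-like cells there were clusters 1 and 7, which held 1191 and 698 cells of WT_2M and 1081 and 368 of WT_6M. KO_2M replicate 1 had 780 and 88 cells in them, replicate 2 had 25 and 29, and KO_6M had 76 and 303, so these calls need not reflect a difference within 1 cell type. The 1 lower gene in neutrophil progenitor-like cells, Igkc, is not read as expression there, since free RNA from other cells can give such counts and no background was measured. In unnamed cells it gave 82 higher and 7 lower genes, led by the mitotic genes Cdca3, Cenpe and Bub1b. These cells mixed clusters of unequal makeup, such as cluster 8 with 50 and 27 wild-type against 480, 473 and 415 knockout cells, so the counts need not reflect a difference within 1 cell type. At resolution 2, where KO_2M replicate 2 had 61 HSC-like cells, edgeR called 1 higher gene, Cd48, and 6 lower genes in HSC-like cells, among them Plk2 and Bgn after Benjamini-Hochberg adjustment. The libraries filled those HSC-like clusters unequally too.

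The libraries of the 2 ages differed in sex-linked transcripts, although all were labelled male. Xist, the RNA of the inactive X chromosome, stood at 0.28, 0.343 and 0.116 CPM in the 2-month libraries and at 2936 and 2394 CPM in the 6-month ones. The Y-linked genes Ddx3y and Eif2s3y stood at 47.0 to 69.3 CPM at 2 months and at 0.0124 to 0.0447 CPM at 6 months. Of 14 erythroid markers, 7 were lower at 6 months over all genes, although the list was not called with an estimated correlation (camera Benjamini-Hochberg adjusted p = 0.961 with an estimated correlation). Klf1, the erythroid master regulator, had a log2 fold change of −2.19 (SE 0.31; edgeR Benjamini-Hochberg adjusted p = 0.021) and Gata1 of −0.94 (SE 0.10; edgeR Benjamini-Hochberg adjusted p = 0.0102). Of 22 cholesterol synthesis genes, 4 rose over all genes, among them Msmo1 (0.79, SE 0.12). The list was not called with an estimated correlation (camera Benjamini-Hochberg adjusted p = 0.961 with an estimated correlation) or, with the preset correlation, without KO_2M replicate 1 (0.0685). The AP-1 genes Jund (−1.63, SE 0.25) and Jun (−1.50, SE 0.29) fell (edgeR Benjamini-Hochberg adjusted p = 0.0271 for Msmo1, 0.0246 for Jund and 0.0447 for Jun). Erythroid progenitor-like cells made up 2.43%, 5.47% and 3.70% of the 2-month libraries and 1.10% and 1.67% of the 6-month ones.

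For age, edgeR called 622 higher and 513 lower genes at 6 months after Benjamini-Hochberg adjustment, and DESeq2 916 and 1066. Left-out libraries moved these counts: 131 and 107 without WT_2M, 91 and 102 without WT_6M, 1114 and 1003 without KO_2M replicate 1, 1600 and 1692 without replicate 2, and 39 and 74 without KO_6M. Fits without either KO_2M library left 1 library per group and so held no replicates. Age cannot be told apart from sex or from the gene models used, since all 3 changed together. Mia2 had no count in any 2-month library and was at 63.2 and 67.5 CPM at 6 months, at least 1510-fold higher. Gm15013, Gm10260, Timm8a1 and the pseudogenes Rpl13a-ps1, Gm10036 and Rpl7a-ps5 gave log2 fold changes of 4.09 to 6.12, while Raver1, Atp5o, Fdx1l, Ints5, Srp54b and Nudt8 gave −9.20 to −12.63. Ribosomal protein genes and their pseudogenes share reads, and their values are uncertain. Rps12 stood at 5442, 5330 and 4984 CPM at 2 months and at 107 and 101 CPM at 6 months. Timm8a1 lost its call without WT_6M (edgeR Benjamini-Hochberg adjusted p = 0.0543), KO_2M replicate 1 (0.0968) or KO_6M (0.0988). Genes under 4-fold that overlapped no other gene, were no pseudogene and lay on neither X nor Y numbered 387 higher and 315 lower among those called.

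Of the lists, camera with the preset correlation called 10 for age. Erythroid progenitor markers were lower in 14 of 14 members, 7 of which fell over all genes and 11 adjusted over the list alone. Cholesterol synthesis genes were higher in 17 of 22, with 4 that rose over all genes, and 9 higher and 1 lower adjusted over the list alone. Immediate early genes had 2 lower over all genes, and 4 lower and 1 higher adjusted over the list alone. Their median log2 ratio of 6 to 2 months, without TMM scaling, was −0.59 in wild type and −0.012 in the knockout. By these ratios the list fell mainly in wild type. Ribosome biogenesis genes were negative in 30 of 31, with 0 and 7 lower. Heat shock genes were negative in 22 of 27, with 0 lower and 1 higher, Dnajb9, by both adjustments. Chromatin regulators had 1 higher over all genes, the X-linked Kdm6a, and 1 higher and 7 lower adjusted over the list alone. Histone genes (32 lower and 4 higher over all genes, 41 and 6 adjusted over the list alone), cytosolic ribosomal proteins (32 and 2, 44 and 3), oxidative phosphorylation genes (7 and 1, 13 and 2) and the sex-linked check genes (4 lower and 2 higher by both) were also called lower. For some lists the direction depended on scaling. Without TMM scaling, the oxidative phosphorylation median log2 ratio of 6 to 2 months was 0.015 in wild type and 0.009 in the knockout. For chromatin regulators it was 0.002 and −0.07. Ribosome biogenesis genes were at 0.06 and −0.36, so by these ratios this list fell only in the knockout. With an estimated correlation none of the 10 was called (camera Benjamini-Hochberg adjusted p = 0.961 with an estimated correlation), and fry called 3. By the camera adjusted p with the preset correlation, the immediate early list lost its call without WT_2M (0.393), WT_6M (0.212) or KO_2M replicate 2 (0.0789), ribosome biogenesis (0.394) and chromatin regulators (0.177) without KO_6M, and cholesterol synthesis without KO_2M replicate 1 (0.0685). Heat shock genes lost it without KO_2M replicate 2 (0.0789) or KO_6M (0.0894), and the sex-linked genes without KO_2M replicate 2 (0.112). Fits for age without WT_2M and without WT_6M both compare the knockout libraries alone, so such losses or gains count once. HSC markers (median −0.13) and G2 and M phase genes (median 0.02) were not called for age. Lists that gained a call without KO_2M replicate 1 were the interferon-stimulated (0.000301), neutrophil (0.00135), macrophage (0.016) and eosinophil lists (0.0391), all lower, and the lymphoid-primed (0.00592) and B-cell progenitor lists (0.00956), both higher. Without replicate 2 the haemoglobin (0.00488), dendritic (0.0244) and macrophage lists (0.0244) were lower. Without KO_6M the eosinophil (3.28e-05), neutrophil (0.00408), haemoglobin (0.00615), macrophage (0.00887), basophil (0.0153) and monocyte lists (0.0169) were lower, as were S phase genes without WT_2M (0.0127) or WT_6M (0.0188). With an estimated correlation none of these was called (camera Benjamini-Hochberg adjusted p of at least 0.962 with an estimated correlation).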

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

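The tests of the knockout itself for the interferon genes, of Xist and the Y-linked genes, and of the sex chromosomes were worded after their results were seen, and the tests with the added clusterings were chosen after the data were seen. The classes without marker genes were set up after the other equal-makeup values were known.

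Some differences had opposite signs at the 2 ages in the planned clustering or in a gene list. The interaction was not tested for the shares. Dendritic cell-like cells were a larger share of the knockout than of the wild type at 6 months, by 0.444 percentage points, and a smaller share in both 2-month pairs. Macrophage-like cells had a difference of −0.102 percentage points at 6 months and positive differences in both 2-month pairs. Without marker genes the macrophage-like differences were 0.356 and −0.15 at 2 months and −0.047 at 6 months, so no reversal was seen there. Haemoglobin and reticulocyte transcripts had a median log2 ratio of 0.16 at 6 months and negative medians in both 2-month pairs, and its interaction did not pass (camera Benjamini-Hochberg adjusted p = 0.0843, and 0.982 with an estimated correlation).

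A gene outside the shared symbols and a sex-linked gene also stood out. Cebpd, a myeloid transcription factor gene listed only in the 6-month tables, was at 11.3 CPM in WT_6M and 36.7 CPM in KO_6M. Xist reached 2394 CPM in the lower of the 2 6-month libraries, although every library was labelled male.

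HSC markers were lower and G2 and M phase genes higher in the knockout libraries, with median log2 ratios over the pairs of −1.13 and 0.39. Thinning every cell to 1 depth left −0.997 and 0.61, so neither pattern came only from deeper cells counting for more in the sums. CPM ratios are already scaled for depth and thinning keeps each cell's expected proportions, so other effects of depth cannot be decided by it. With equal numbers of cells of each class built without marker genes, the HSC median shrank to −0.22. These classes were still named from the HSC markers, so equal numbers of HSC-like cells tend to even out the markers too. This setting therefore cannot decide whether class makeup accounts for the pattern. In addition, 1965 cells of KO_2M replicate 2 lay in an unnamed interferon-high cluster closest to HSC. Planned and library-centred classes both gave −0.26, but 13 of the 14 markers helped to build them. For the G2 and M phase genes equal makeup gave 0.12 with library-centred classes and −0.0068 without marker genes, but 28 of the 52 genes helped to build the classes, so class makeup and a difference within classes cannot be told apart, and the genotype and the unknown sort gate both stay open.

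Interferon-stimulated genes were higher in KO_2M replicate 2 than in WT_2M. The lowest median log2 ratio over 7 library-centred classes was 0.865, which argues against class makeup. Replicate 1, of the same genotype and age, had a median of −0.22, which argues against the knockout alone as the cause. Some feature of that library or its mice could be the source, and no table here names it. KO_6M had medians of 0.31 to 0.88 in the same classes. The interaction for this list did not pass (camera Benjamini-Hochberg adjusted p = 0.821). It drew on 2 KO_2M libraries with medians of −0.22 and 0.91, so it cannot decide on a later effect of the knockout, which stays open.

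The 6-month libraries differed from the 2-month ones in more than age. Xist at 2394 CPM or more, with Y-linked genes near 0, is consistent with female mice or a wrong sex label at 6 months. The sex chromosomes held 2.76% of the called genes against 3.41% of the others, which argues against sex chromosome dosage for most of them, while sex acting on autosomal genes was not tested. Of called genes at 4-fold or more, 23.2% overlapped another gene or were pseudogenes against 8.04% of genes not called, so gene models counted differently may account for part of these. Age itself stays open, as untested.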

How the results depend on the processing

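The library-centred and marker-free settings and the tests within an age were chosen after the data were seen. No paired analysis was possible because no label pairs the libraries. Of 240 alternatives to the main results, 170 stayed within the allowed range, 63 moved and 7 reversed. For counts of genes or lists only the numbers were compared, not which genes or lists were called. A main count of 0 stayed the same only as another 0. Only differences in share could be labelled reversed. For named genes 462 of 504 kept their side of the threshold, 39 came to pass and 3 no longer passed. The cause of these moves was not tested.

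With DESeq2 as the test, genotype gave 182 higher and 176 lower genes, age 1066 lower, the interaction 8 higher, and lymphoid-primed, megakaryocyte and unnamed cells 1, 3 and 12 genes. Within an age it gave 2 higher and 33 lower genes at 2 months and 13 and 2 at 6 months. Thinned cells gave 1 lower gene for genotype. Equal class makeup gave 1000 higher and 963 lower genes for age, and 1346 and 1304 with library-centred classes. An estimated correlation called 0 lists for genotype and 0 for age, and fry 0 and 3.

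Without the low-count filter, erythroid, lymphoid-primed, megakaryocyte and monocyte cells had 8, 32, 11 and 64 genes called. Resolution 0.5 gave 1 gene in lymphoid-primed and 5 in megakaryocyte cells, and resolution 2 gave 3 and 2. Library-centred clustering gave 2 in megakaryocyte and 89 in unnamed cells.

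The HSC-like difference in share was −0.845 percentage points with the stricter cell filter and −28.6 at resolution 0.5. With the stricter filter, which kept as few as 139 cells in WT_6M, erythroid (−1.64), B-cell (−1.55) and basophil (−0.499) differences reversed. The lymphoid-primed difference, −0.521, reversed to 8.82 with library-centred clustering, 0.655 at resolution 2, 1.86 without WT_6M and 1.35 without KO_2M replicate 2, and was −7.17 without marker genes. The basophil difference was 0.301 without marker genes. A minimum mean of 5 CPM gave 24 genes lower in all 3 pairs and 297 apart between the KO_2M libraries, and 100 CPM gave 2 and 28.

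Leaving out 1 library in turn gave 0 to 467 higher and 0 to 607 lower genes for genotype, and 39 to 1600 higher and 74 to 1692 lower for age. The range was 0 to 120 in erythroid, 0 to 232 in lymphoid-primed, 0 to 169 in megakaryocyte, 0 to 16 in monocyte and 0 to 660 in unnamed cells. The lymphoid-primed difference ranged from −2.90 to 1.86 and the basophil difference from 0.329 to 0.703 percentage points. A lone library of a group was then assumed to vary like the others, except without either KO_2M library. Those fits left 1 library per group, so their counts rest on no spread between replicates.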

Other observations

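The genes in these paragraphs were chosen after their values were seen, and the lists were fixed beforehand. Mature neutrophil markers, which encode granule and antimicrobial proteins, had 8 of 10 members negative in the knockout (median log2 fold change −1.29, camera Benjamini-Hochberg adjusted p = 0.249). S100a9 stood at 278 and 285 CPM in wild type against 272, 24.8 and 67.1 CPM. The immunoglobulin heavy-chain gene Ighm stood at 1017 and 835 CPM against 610, 79.9 and 204 CPM, and mature B cell markers had 6 of 8 negative (median −0.60, camera Benjamini-Hochberg adjusted p = 0.0667). Inflammatory cytokine and NF-kB genes had 15 of 22 negative (median −0.23, camera Benjamini-Hochberg adjusted p = 0.0667), with the chemokine gene Ccl4 at 29.5 and 29.8 CPM against 19.7, 10.7 and 14.1 CPM. In each of these lists 0 genes passed over all genes and 0 adjusted over the list alone. Fits without KO_6M and without WT_6M test the same 2-month contrast. Leaving out 1 library gave calls of lower expression by camera Benjamini-Hochberg adjusted p. These were mature neutrophil markers without KO_2M replicate 1 (0.00197), mature B cell markers without KO_2M replicate 1 (0.0185), KO_6M (0.0328) or WT_6M (0.0329), and inflammatory genes without KO_2M replicate 2 (0.0487). With an estimated correlation none of these was called (adjusted p of at least 0.802 with an estimated correlation). An equal class makeup called mature neutrophil markers higher with planned classes (0.046) and lower with library-centred ones (0.0234), and mature B cell markers lower with the latter (0.00491). With an estimated correlation these were not called (adjusted p = 0.783 and 0.719 with an estimated correlation), and the setting decides nothing for lists whose genes helped to build the classes.

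Megakaryocyte progenitor markers had 5 of 10 members negative (median −0.10, camera Benjamini-Hochberg adjusted p = 0.564), although megakaryocyte progenitor-like cells were a larger share of each knockout library, except in replicate 1 at 2 months with the stricter cell filter. Gp9, a subunit of the platelet von Willebrand factor receptor, was lower adjusted over the list alone and did not pass over all genes (log2 fold change −0.52, SE 0.10). Basophil or mast cell progenitor-like cells made up 0.448% and 0.238% of wild-type cells against 0.600%, 0.485% and 0.847% of knockout cells without marker genes (two-sided exact permutation p = 0.2). The planned clustering gave 0.665% and 0.291% against 0.941%, 1.10% and 0.945% (two-sided exact permutation p = 0.1, the smallest possible). The stricter cell filter reversed this difference. Lymphoid-primed progenitor-like cells made up 8.14% and 31.1% against 11.3%, 1.76% and 24.3% without marker genes (two-sided exact permutation p = 0.6), and 3.23% and 7.99% against 4.19%, 1.35% and 9.72% in the planned clustering (p = 0.9 by the same exact test).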
